A study of Mus musculus with 2 samples.

How the data were processed

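Total RNA from hippocampal tissue of female B6CASTF1/J mice, the first-generation hybrid of a C57BL/6J and a CAST/EiJ parent, was sequenced in 2 libraries. The labels describe the tissue as a layer of the hippocampus, give an age of 36 days and an RNA input of 300 ng, and number the libraries as biological replicates 1 and 2. The labels give each library a biosample of its own and both libraries 1 shared donor identifier, so they do not say outright that the tissue came from separate mice. The spread given here is therefore that between these samples. A set of external spike-in RNAs (the ERCC mix) had been added to both, and its profile is named in the labels for stranded, ribosomal-RNA-reduced libraries. The RNA was purified with a column kit for animal tissue, per the labels' protocols.

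3 tables per library were used, all on mouse genome build mm10. In the gene table and in the first transcript table the authors deposited expected counts, which need not be whole because a read that matches several transcripts is divided among them, per the file headers. The same tables hold TPM (transcript abundance scaled to RNA length and to the whole library) as the authors' software gave it, per the file headers. The first transcript table also holds the percent of its gene's TPM that each transcript takes, as deposited. The second transcript table holds the authors' estimated counts and TPM from a second quantification, per the file headers. The column names of the first set are those RSEM writes and those of the second set are those kallisto writes. The software and its versions are not given in the sources used here, and neither is whether counting used the strand. Reads from overlapping genes on opposite strands can therefore be mixed in either gene's count. In the first set, effective lengths lay 99 bases below the RNA length. In the second they lay 339.06 and 325.02 bases below it for long RNAs in replicates 1 and 2, the fragment lengths assumed there. The deposited bounds on TPM in the gene and first transcript tables were read and not used further.

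All 55536 gene identifiers matched GENCODE release M21, which gave symbols, gene types and coordinates. The gene tables also held 96 spike-in entries and 26248 entries with a number in place of a gene name. The numbered entries took 4 counts in replicate 1 and 5 counts in replicate 2, or 1.42e-05% of all counts, and were left out of library sizes. Second-quantification counts were summed over the transcripts of each gene, and 86 genes had no transcript there. A gene whose expected count differed from a whole number by more than 0.005 in either library was treated as sharing reads with another gene, and its value as uncertain.

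The single group allowed no test between conditions. With 1 library on each side, differences between the replicates were described by rules of size, with no p-value. The tests and gene lists of the report, most alternative settings and the rule for naming genes were fixed before the data were examined, and what was added later is named as such in the closing paragraphs. A gene was called detected at 1 TPM or more in both libraries. Expected counts were rounded to whole numbers and scaled with edgeR 4.0.16 (TMM) in R 4.3.3. The spread was edgeR's common dispersion over the 18246 genes with a mean count of 10 or more, given as the biological coefficient of variation, the square root of the dispersion. Log2 ratios are replicate 2 over replicate 1, on counts scaled to library size (CPM) with a prior count of 0.5. They were compared over the 12651 genes with a mean count of 100 or more, and a gene was called apart where the ratio exceeded 2-fold. For a gene with 0 counts in 1 library the fold was taken against a floor of 3 counts in that library and is a lower bound. A list was compared where at least 3 members had a mean count of 100 or more. Its median log2 ratio was placed among those of 10000 random lists of the same size, matched on mean count in 20 bins, and called outside where it fell beyond the central 95%. These percentiles describe the 2 libraries and are not p-values. The major transcript of a gene, the one with the highest TPM, was compared between the quantifications for genes at 10 TPM or more with at least 2 annotated transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 did the rest. DESeq2 1.42.0 gave alternative size factors. Other alternatives were total-count and spike-in scaling, the deposited TPM, the second quantification, other count and TPM minimums, other folds and each replicate alone.

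There were 16 lists of cell type and subfield markers, 10 of neighbouring or unrelated tissues, 1 of Y-linked genes and 19 of gene functions, besides a panel of 22 genes for isoforms. The named genes are, in each list, the 3 members with the highest mean TPM and every member over 2-fold apart, then the 12 highest and 12 lowest log2 ratios among genes with a symbol, the 20 genes with the highest mean TPM, the 8 genes whose major transcript differed between the quantifications at the highest TPM, and the isoform panel. Genes named outside this rule are marked as chosen after their values were seen. Some genes that met the rule are not reported here.

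The steps were tested on simulated data. For the spread and the 2-fold rule, counts of the 18246 genes were simulated at a biological coefficient of variation of 0.1 with 200 changed genes. The recovered value was 0.101, the rule called 99% of the genes changed 3-fold and 100% of those changed 6-fold, and it called 2 unchanged genes. At a simulated coefficient of 0.3 the recovered value was 0.298, and the rule called 86% of the 3-fold genes, 100% of the 6-fold genes and 1394 unchanged genes. For the list comparison, all 100 lists of 8 genes shifted by 0.5 on the log2 scale lay outside the central 95%, and so did 6 of 100 lists with no shift. That shift is far beyond the random range, which was −0.106 to 0.042 for the 8 CA1 genes. Most list medians reported here are smaller, and the simulation does not tell how often shifts of their size are found. Summed gene counts were 32299053 and 30010758 in replicates 1 and 2. A count of 0 allows up to 3 counts, or 0.0925 and 0.0996 CPM of the totals with spike-ins, which covers counting error only. The counts of the 2 libraries differed by more than sampling noise, with a mean chi-square of 8.86 per gene over the 18246 genes with a mean count of 10 or more. Genes far apart, such as Ttr, weigh heavily in that mean, and without the genes over 2-fold apart the biological coefficient of variation was 0.0614. The libraries were treated as 2 samples because the labels number them so. Separate libraries from 1 donor could exceed sampling noise too, so the chi-square does not tell whether the mice were separate. The 300-base signal recognition particle RNA genes Rn7s1 and Rn7s2 had identical expected counts, as near-identical copies that share their reads do.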

Results

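Gene expression was profiled in the hippocampus of young female B6CASTF1/J mice by total RNA sequencing. The design held 1 group with 2 replicates, each from 36-day-old tissue and 300 ng of RNA. Summed expected counts, spike-ins included, were 32443497 in replicate 1 and 30125183 in replicate 2. The labels state no comparison between conditions, so the measurements are levels, given with the spread between the 2 libraries. That spread does not cover the difference between the 2 quantifications, and TPM is that of the first unless the second is named. Values are given as mean ± SD over n = 2 libraries unless each replicate is named. For a list, the SD is that of its 2 medians and does not measure how far its members differed between the libraries.

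Of 55536 annotated genes, 14590 were detected at 1 TPM or more in both libraries, among them 12666 protein-coding genes and 1095 long non-coding RNA genes. Protein-coding RNA took 78.3% ± 0.40 of the expected counts. RNA from the mitochondrial genome took 8.00% ± 0.096, of which the ribosomal RNAs mt-Rnr1 and mt-Rnr2 made up 6.47% ± 0.27 and the mitochondrial mRNAs 1.52% ± 0.17. Small structural RNAs took 6.14% ± 0.21, long non-coding RNAs 5.89% ± 0.16, pseudogenes 1.27% ± 0.020 and spike-ins 0.413% ± 0.046.

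The RNA component of the signal recognition particle, encoded by Rn7s1 (mm10, chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481), was the most abundant RNA by TPM. The pair took 4.79% ± 0.11 of the counts and 32.5% ± 0.19 of the TPM. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, followed at 57645 ± 1740 TPM, and Rpph1, the RNA of ribonuclease P, was at 7979 ± 60.6 TPM. Rmrp, the RNA of ribonuclease MRP, is annotated at 2 overlapping places, whose values were 3164 ± 166 and 2367 ± 9.52 TPM. With TPM in place of counts the small structural RNAs took 42.5% ± 1.04 and protein-coding genes 40.8% ± 0.75. In the second quantification these small RNAs were almost absent, at 0.138% ± 0.035 of TPM. Protein-coding genes took 73.9% ± 0.073 of TPM there, so levels in TPM depend on the quantification by more than the SD shows.

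The most abundant long RNAs were mt-Rnr2 at 42070 ± 907 TPM, mt-Rnr1 at 30012 ± 837 TPM and Gm26917 at 14070 ± 419 TPM. Gm26917 (chromosome 17, 39843013 to 39846341) and Gm42418 (chromosome 17, 39846958 to 39848788), neighbouring non-coding genes whose sequence is related to the ribosomal RNA repeat, together took 3.03% ± 0.089 of the counts. They are part of the 5.89% given above for long non-coding RNAs. Malat1, a nuclear-retained non-coding RNA, was at 5016 ± 191 TPM. Among the 20 genes with the highest TPM were also mt-Co1 at 4992 ± 505 TPM, mt-Cytb at 2833 ± 240 TPM, mt-Nd1 at 2605 ± 296 TPM and mt-Atp8 at 2089 ± 156 TPM. The pseudogenes Gm28661 (6470 ± 466 TPM), Gm10925 (5327 ± 55.9 TPM) and Gm28437 (4107 ± 186 TPM) lie side by side on chromosome 1 between 24613189 and 24615565. These pseudogenes and mt-Co1 share reads, so their values are uncertain. The shares of the counts given above for pseudogenes and for mitochondrial mRNAs include them and are uncertain too. In replicate 1, Gm10925 had 73117 counts in the first quantification and 18079 in the second. The small nuclear RNA genes Gm23444 and Gm23472 shared 1 value of 2386 ± 966 TPM. These 20 genes held 18.4% ± 0.45 of the counts.

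Pan-neuronal and excitatory neuron genes had the highest medians of the cell type lists. All 10 pan-neuronal genes were detected, with a list median of 173 ± 21.8 TPM, led by the exocytosis gene Snap25 at 788 ± 89.1 TPM, the dendritic microtubule protein gene Map2 at 440 ± 10.3 TPM and the neuronal enolase gene Eno2 at 396 ± 31.5 TPM. The excitatory neuron list was complete as well, at a median of 93.4 ± 0.018 TPM. Its leading genes were the kinase gene Camk2a at 1241 ± 87.1 TPM, the postsynaptic protein gene Nrgn at 627 ± 35.5 TPM and the vesicular glutamate transporter gene Slc17a7 at 548 ± 27.2 TPM. All 12 GABAergic interneuron genes were detected at a lower median of 22.3 ± 0.81 TPM, with the neuropeptide genes Sst at 174 ± 9.55 TPM and Npy at 56.8 ± 7.07 TPM and the GABA-synthesising Gad1 at 146 ± 6.99 TPM.

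Markers of each hippocampal subfield were present. The CA1 list was detected in full at a median of 25.5 ± 1.52 TPM, led by Mpped1 at 66.8 ± 0.31, Wfs1 at 62.7 ± 11.8 and Fibcd1 at 45.8 ± 0.13 TPM. Of the CA2 list, 7 of 8 genes were detected, at 23.4 ± 0.014 TPM, with Pcp4 at 113 ± 5.64, Necab2 at 44.4 ± 3.10 and Rgs14 at 41.5 ± 3.32 TPM. The CA3 list was complete at 22.0 ± 2.55 TPM, with Cpne4 at 52.3 ± 9.74, Homer3 at 30.8 ± 5.47 and Bok at 29.0 ± 4.09 TPM. The dentate granule neuron list was complete at 20.9 ± 0.62 TPM, with the granule neuron transcription factor gene Prox1 at 39.9 ± 2.99, C1ql2 at 37.5 ± 2.86 and Stxbp6 at 31.0 ± 2.81 TPM. The medians of these 4 lists ran from 20.9 to 25.5 TPM, and with 2 libraries no order among them was drawn. Of the mossy cell list 5 of 6 genes were detected, at 12.9 ± 0.25 TPM, with Ociad2 at 52.0 ± 10.4, Calb2 at 21.9 ± 2.18 and Ajap1 at 20.1 ± 1.19 TPM.

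Immature and dividing cells left a weaker trace. In the newborn neuron list 5 of 8 genes were detected, with a median of 4.61 ± 0.32 TPM and Tubb2b at 98.8 ± 4.42, Neurod1 at 13.4 ± 0.23 and Sox11 at 9.70 ± 0.13 TPM. Only 2 of 8 proliferation genes reached 1 TPM in both libraries, Hmgb2 at 1.97 ± 0.37 and Top2a at 1.45 ± 0.18 TPM, and the list median was 0.568 ± 0.046 TPM.

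All 10 astrocyte genes were detected, at a median of 76.5 ± 1.70 TPM, with the glutamate transporter genes Slc1a2 at 656 ± 18.7 and Slc1a3 at 155 ± 5.21 TPM and the glycolytic Aldoc at 310 ± 3.88 TPM. All 10 oligodendrocyte genes were detected at 71.1 ± 11.6 TPM, and the myelin genes Mbp and Mobp stood at 575 ± 117 and 155 ± 38.5 TPM. Oligodendrocyte precursor genes (8 of 8) had a median of 8.79 ± 0.94 TPM, with Olig1 at 49.9 ± 5.37, Gpr17 at 18.4 ± 0.13 and Pdgfra at 15.2 ± 0.57 TPM. Microglia genes (11 of 11) had a median of 14.6 ± 0.23 TPM, with Csf1r at 29.3 ± 3.15 and C1qa at 19.6 and 18.5 TPM in replicates 1 and 2. Vascular genes were lower. Endothelial genes (9 of 9) had a median of 7.42 ± 0.47 TPM, led by Ly6c1 at 23.7 ± 0.021, Cldn5 at 18.7 ± 0.45 and Slco1a4 at 14.1 ± 0.40 TPM. Mural cell genes (7 of 8) had a median of 4.61 ± 0.87 TPM, led by Vtn at 23.1 ± 2.07, Rgs5 at 20.3 ± 1.16 and Acta2 at 6.28 ± 1.12 TPM. Over the 16 lists, 129 of 141 distinct marker genes were detected.

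**Figure D1:**
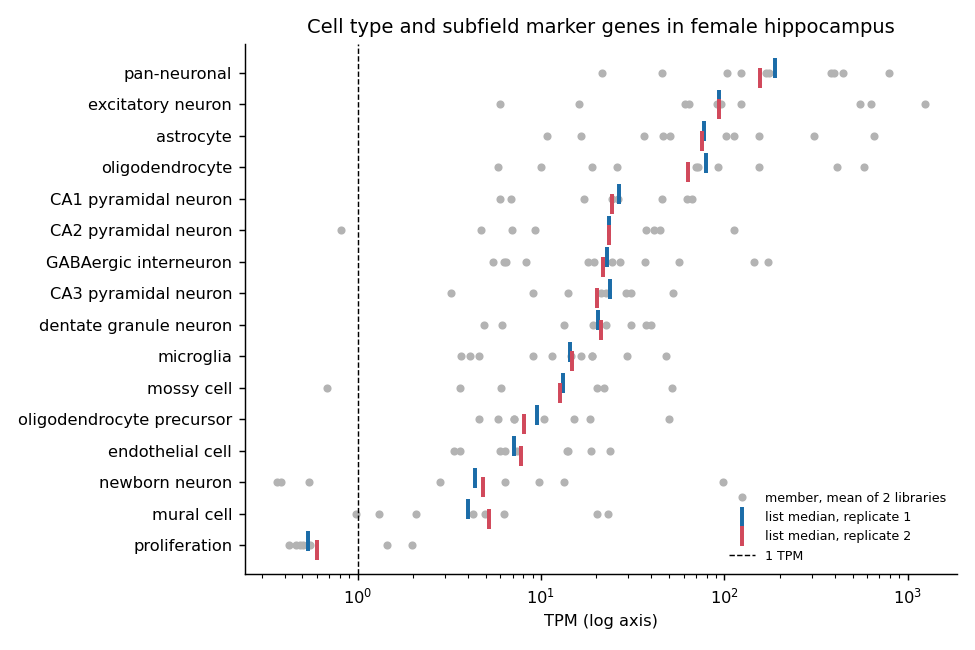
Level in TPM (log axis) of each marker gene in 16 cell type and subfield lists, as grey points for the mean of 2 libraries, with the list median in replicate 1 (blue bar) and replicate 2 (red bar) and a dashed line at 1 TPM. Pan-neuronal genes lie highest, with a mean of the medians of 173 TPM, and proliferation genes lowest, at 0.568 TPM.

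Of 82 distinct genes listed for neighbouring and unrelated tissues, 81 matched the annotation and 43 were detected. Detection alone does not tell whether such an RNA came from that tissue or from cells of the hippocampus, and this was not tested. Hemoglobin genes marked blood, with 5 of 6 blood cell genes detected at a median of 79.7 ± 5.11 TPM and Hbb-bs, Hba-a2 and Hba-a1 at 168 ± 10.3, 144 ± 0.71 and 144 ± 14.4 TPM. Of 8 cerebral cortex genes 7 were detected, at a median of 10.3 ± 0.81 TPM, with Hs3st4 at 37.8 ± 7.16, Fezf2 at 17.5 ± 1.05 and Tle4 at 16.9 ± 0.20 TPM. Thalamus (6 of 8 detected, median 3.75 ± 0.057 TPM) was led by Rora at 13.2 ± 1.65, Plekhg1 at 6.81 ± 0.39 and the glutamate transporter gene Slc17a6 at 5.21 ± 0.62 TPM. Striatum (6 of 8, 3.27 ± 0.095 TPM) was led by Ppp1r1b at 22.1 ± 2.47, Penk at 16.2 ± 1.88 and Rgs9 at 5.49 ± 0.53 TPM. Of 7 cerebellum genes matched, 3 were detected, Calb1 at 67.8 ± 2.42, Zic2 at 6.75 ± 0.24 and Zic1 at 5.19 ± 0.44 TPM, and the list median was 0.715 ± 0.40 TPM. None of 8 hypothalamus genes reached 1 TPM in both libraries, the highest being Pomc at 0.650 ± 0.085, Avp at 0.580 ± 0.18 and Trh at 0.475 ± 0.078 TPM (list median 0.148 ± 0.025). Of 10 genes of other organs the lung gene Sftpc was detected, at 1.52 ± 0.61 TPM, while Myh6 was at 0.990 ± 0.75 and Apoa2 at 0.420 ± 0.071 TPM, and the list median was 0.0900 ± 0.021 TPM. Ependymal genes (4 of 8, 1.68 ± 0.49 TPM) were led by Rarres2 at 5.95 ± 0.75, Rsph1 at 5.46 ± 1.59 and Fam183b at 2.46 ± 0.15 TPM.

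The sex-linked genes followed the female label. Xist, the RNA that silences an X chromosome, was at 75.4 ± 7.20 TPM, beside Ddx3x at 74.5 ± 2.01 and Eif2s3x at 58.8 ± 0.86 TPM, and 5 of 6 genes of the X-linked list were detected at a median of 42.3 ± 0.20 TPM. None of 6 Y-linked genes was detected. Ddx3y, Uty and Kdm5d had at most 2 counts in a library, and the other three, Zfy1, Usp9y and Eif2s3y, named after their values were seen, had 0 counts in both, which allows up to 0.0925 and 0.0996 CPM in replicates 1 and 2.

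Synaptic genes were expressed at high levels. Presynaptic terminal genes (12 of 12 detected) had a median of 194 ± 17.4 TPM, with the vesicle protein genes Syp at 780 ± 47.0 and Vamp2 at 382 ± 17.1 TPM and the fusion regulator gene Cplx2 at 375 ± 16.9 TPM. Postsynaptic density genes (11 of 11) had a median of 110 ± 4.44 TPM, with Camk2b at 438 ± 6.37, the scaffold gene Dlg4 at 347 ± 11.2 and Shank1 at 230 ± 7.10 TPM. All 15 ionotropic glutamate receptor genes were detected (median 42.0 ± 0.95 TPM), led by Gria1 at 276 ± 10.6, Gria2 at 264 ± 5.71 and Grin1 at 166 ± 9.60 TPM. Of the metabotropic glutamate receptors 7 of 8 were detected (25.7 ± 0.81 TPM), with Grm5 at 103 ± 1.56, Grm7 at 29.1 ± 0.98 and Grm2 at 27.5 ± 2.16 TPM. All 12 GABA-A receptor subunit genes were detected (56.0 ± 0.55 TPM), with Gabra5 at 69.6 ± 2.02 TPM.

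Energy metabolism genes were abundant too. The 13 mitochondrially encoded protein genes had a median of 1669 ± 434 TPM, and the nuclear-encoded oxidative phosphorylation genes (12 of 12) one of 156 ± 5.96 TPM, with Atp5b at 698 and 715 TPM in replicates 1 and 2, Cox4i1 at 433 ± 3.54 and Ndufa4 at 313 ± 17.3 TPM. Heat shock genes (8 of 8) had a median of 78.9 ± 11.5 TPM, led by the chaperone genes Hspa8 at 868 ± 106, Hsp90aa1 at 425 ± 37.9 and Hspa5 at 144 ± 15.6 TPM. Core clock genes (14 of 14, 17.4 ± 0.36 TPM) were led by Tef at 119 ± 1.26, Cry2 at 37.5 ± 0 and Per1 at 35.4 ± 5.76 TPM. Of the steroid receptors 4 of 6 were detected (5.22 ± 0.067 TPM), with the mineralocorticoid receptor gene Nr3c2 at 58.1 ± 3.99 and the glucocorticoid receptor gene Nr3c1 at 31.7 ± 2.78 TPM. Interferon-stimulated genes were low, with 3 of 10 detected and a median of 0.738 ± 0.17 TPM, although Ifi27 stood at 41.5 ± 2.74 and Bst2 at 2.13 ± 0.28 TPM.

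Imprinted genes, expressed from 1 parental copy, were detected in 18 of 20 cases at a median of 38.7 ± 9.33 TPM, led by Meg3 at 928 ± 0.38, Rian at 451 ± 11.7 and Snrpn at 342 ± 17.9 TPM. The tables hold no counts per parental allele. All 10 long non-coding RNAs of that list were detected (156 ± 5.55 TPM). In the list of RNA polymerase III and small structural RNAs 9 of 10 were detected (2808 ± 80.8 TPM), with 0 counts in both libraries for the other, Rny3, named after its value was seen. Replication-dependent histone genes (10 of 10, 17.7 ± 0.39 TPM) were led by Hist1h4h at 146 ± 1.14, Hist1h4d at 56.5 ± 4.91 and Hist1h1c at 21.7 ± 0.55 TPM.

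The replicates lay close together over most genes. The biological coefficient of variation was 0.0899, 93.8% of the 12651 compared genes lay within 1.25-fold, and across the 18246 genes with a mean count of 10 or more, which are not independent replicates, the counts correlated with a Pearson r of 0.989 on log2 CPM and a Spearman rho of 0.993. The spike-in RNAs gave another relation. Over the 41 spike-ins with a mean count of 10 or more the median log2 ratio of raw counts was −0.34, against −0.09 for endogenous genes, so that the spike-ins were 0.841-fold as high in replicate 2 relative to endogenous RNA, and 38 of the 41 lay below the endogenous median. Scaling to the spike-ins moved every log2 ratio by 0.26 and the median of all genes from −0.01 to 0.25. Ratios are given relative to TMM scaling, and a value between −0.26 and 0 turns positive under spike-in scaling.

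Genes of the choroid plexus, the secretory tissue that makes cerebrospinal fluid, set the libraries apart most. All 7 list members with a mean count of 100 or more were over 2-fold higher in replicate 2, with a median log2 ratio of 4.28, at the 100 percentile of random lists. The thyroid hormone carrier gene Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321) had 533 counts (20.8 TPM) in replicate 1 and 30135 counts (1237 TPM) in replicate 2, a 59.6-fold difference. Clic6 was 36.1-fold, Slc4a5 29.0-fold, the water channel gene Aqp1 19.5-fold, F5 13.5-fold, Sostdc1 12.9-fold and Kl 3.84-fold higher. Of the 10 genes listed, 3 reached 1 TPM in both libraries, and the list median was 0.295 TPM in replicate 1 and 6.00 TPM in replicate 2. Meningeal fibroblast genes were higher in replicate 2 as well, 7 of 7, with a median log2 ratio of 0.68. Igf2 (chromosome 7, 142650766 to 142666816), a growth factor gene whose count includes shared reads, was 2.57-fold higher, from 24.7 to 62.5 TPM, while Dcn and the collagen gene Col1a1 had log2 ratios of 0.57 and 0.68. That list was detected in full at a median of 5.19 ± 1.93 TPM.

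**Figure D2:**
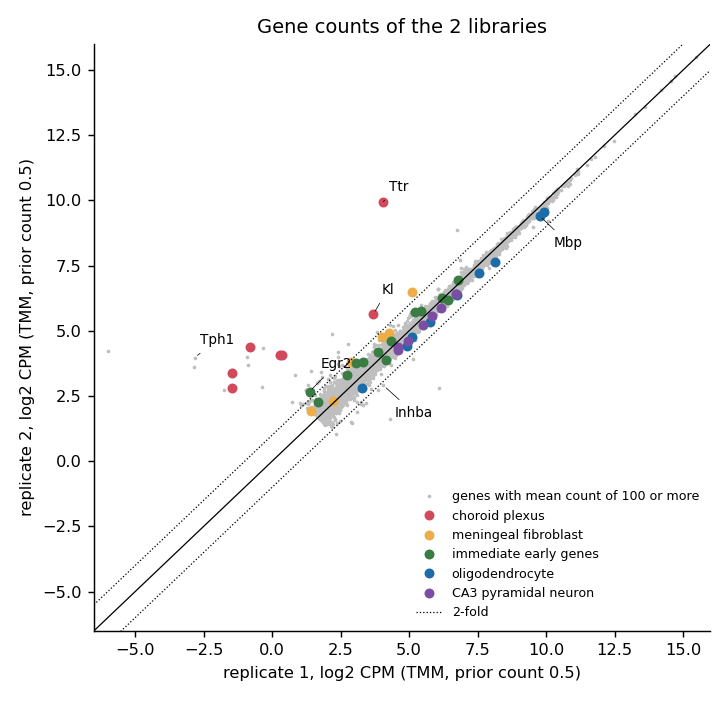
Counts scaled to library size (CPM) of the 12651 genes with a mean count of 100 or more in replicate 1 (x axis) and replicate 2 (y axis), both as log2 with TMM scaling and a prior count of 0.5, with 5 gene lists in colour, the line of equality and dotted lines at 2-fold. The choroid plexus genes (red) lie above the 2-fold line, Ttr by 59.6-fold, while oligodendrocyte (blue) and CA3 (purple) genes lie just below equality, where spike-in scaling adds 0.26 to each log2 ratio.

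Activity-regulated genes split by list, and the timing of their induction was not measured. Of 13 immediate early genes, which are induced within minutes of neuronal firing, 11 were higher in replicate 2, with a median log2 ratio of 0.35 at the 100 percentile, or 0.22 at the same percentile among members with a mean count of 500 or more. Egr2 was 2.46-fold higher (82 and 192 counts), Junb had a log2 ratio of 0.51 and Fos, chosen after its value was seen, one of 0.70, whereas Arc, the most abundant at 53.1 ± 4.04 TPM, had 0.16 and Egr1 0.04. The exceptions, named after their values were seen, were Egr3 (−0.24) and Fosb (−0.25), and both lie above 0 under spike-in scaling, which moves the median of all genes to 0.25. All 8 genes of the list named late activity-regulated, Nr4a3 and Ptgs2 among them, were lower, with a median of −0.32, or −0.06 under spike-in scaling. Inhba, which encodes an activin subunit (chromosome 13, 16011851 to 16031621), was 2.23-fold lower, with 535 and 227 counts. Rasgrp1, Vgf and Nr4a3 had −0.22, −0.26 and −0.16. Immediate early genes were detected in full at a median of 9.09 ± 1.92 TPM and those of the late list at 14.9 ± 3.45 TPM. 

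Several cell type and subfield lists differed as well. Oligodendrocyte genes were lower in replicate 2 in 10 of 10 cases, with a median log2 ratio of −0.35 (Mbp −0.35, Mobp −0.51) that was −0.09 under spike-in scaling. CA3 genes were lower in 7 of 7 cases, with a median of −0.31 (Cpne4 −0.31, Homer3 −0.31, Bok −0.36) that was −0.05 under spike-in scaling. Dentate granule neuron genes were higher, 6 of 8 with a median of 0.15 (Prox1 0.14, C1ql2 0.16). Pan-neuronal genes (−0.16), CA1 genes (−0.13), blood cell genes (−0.18), heat shock genes (−0.24) and mitochondrially encoded protein genes (−0.23) lay below random lists, and each of these 5 medians turned positive under spike-in scaling, to 0.10, 0.13, 0.08, 0.02 and 0.03. That scaling moves all genes alike and cannot move a list against random lists, so their percentiles of 0.12, 0.74, 0.1, 0 and 0 stayed below the central 95%. The blood cell list came inside it at a mean count of 10 or more (percentile 3.32) and of 500 or more (4.16). Glucocorticoid-responsive genes (10 of 10 detected, 37.9 ± 4.24 TPM) lay above, at 0.09, although their most abundant members Mt1 and Mt2 had 0.01 and −0.10 and Sgk1 0.09, and the list came inside with the deposited TPM (percentile 97.3). Metabotropic glutamate receptors lay above at 0.11, a median that was −0.03 among members with a mean count of 500 or more. They came inside there, with the deposited TPM (97.1) and with the mean in place of the median (93.7). The imprinted (0.02), long non-coding (0.01) and small structural RNA (0.02) lists lay just outside the upper limit. With the deposited TPM all 3 came inside, at percentiles of 87.1, 95.9 and 93.0, and with the other scalings of counts they lay at 97.3 to 97.4. Those scalings move all genes nearly alike, so that last change came from a new random draw. The long non-coding list was inside also in the second quantification (96.9), at a mean count of 10 or more (96.8) and with the mean in place of the median (97.2), and the small structural list at a mean count of 10 or more (89.1). The median of the imprinted genes was −0.00084 with the deposited TPM and that of the long non-coding RNAs −0.0058 in the second quantification. Within the imprinted list Cdkn1c, a cell cycle inhibitor gene, was 2.91-fold higher, besides Igf2.

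In all, 17 of 40 lists lay outside the central 95% of random lists, where 2 would by chance, and the 3 lists just named with percentiles from 97.6 to 98.0 depend on the random draw. The 23 lists inside had these medians: excitatory neuron −0.11, CA2 −0.09, mossy cell 0.03, newborn neuron 0.01, GABAergic interneuron −0.09, astrocyte −0.02, oligodendrocyte precursor −0.03, microglia −0.05, endothelial cell 0.05, mural cell 0.13, cerebral cortex −0.11, thalamus 0.02, striatum 0.14, cerebellum 0.10, ionotropic glutamate receptors −0.02, GABA-A receptor subunits −0.08, postsynaptic density −0.06, presynaptic terminal −0.08, core clock 0.01, steroid receptors −0.03, X-linked 0.02, nuclear-encoded oxidative phosphorylation −0.04 and replication-dependent histones −0.01. The proliferation, ependymal, hypothalamus, other organs, interferon-stimulated and Y-linked lists had too few members with a mean count of 100 or more. At a mean count of 10 or more the cerebellum (1.15), mural cell (0.33) and X-linked (0.06) lists lay above random lists, and so did the ependymal list (0.60), while the other organs (−0.77) and interferon-stimulated (−0.27) lists lay below.

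**Figure D3:**
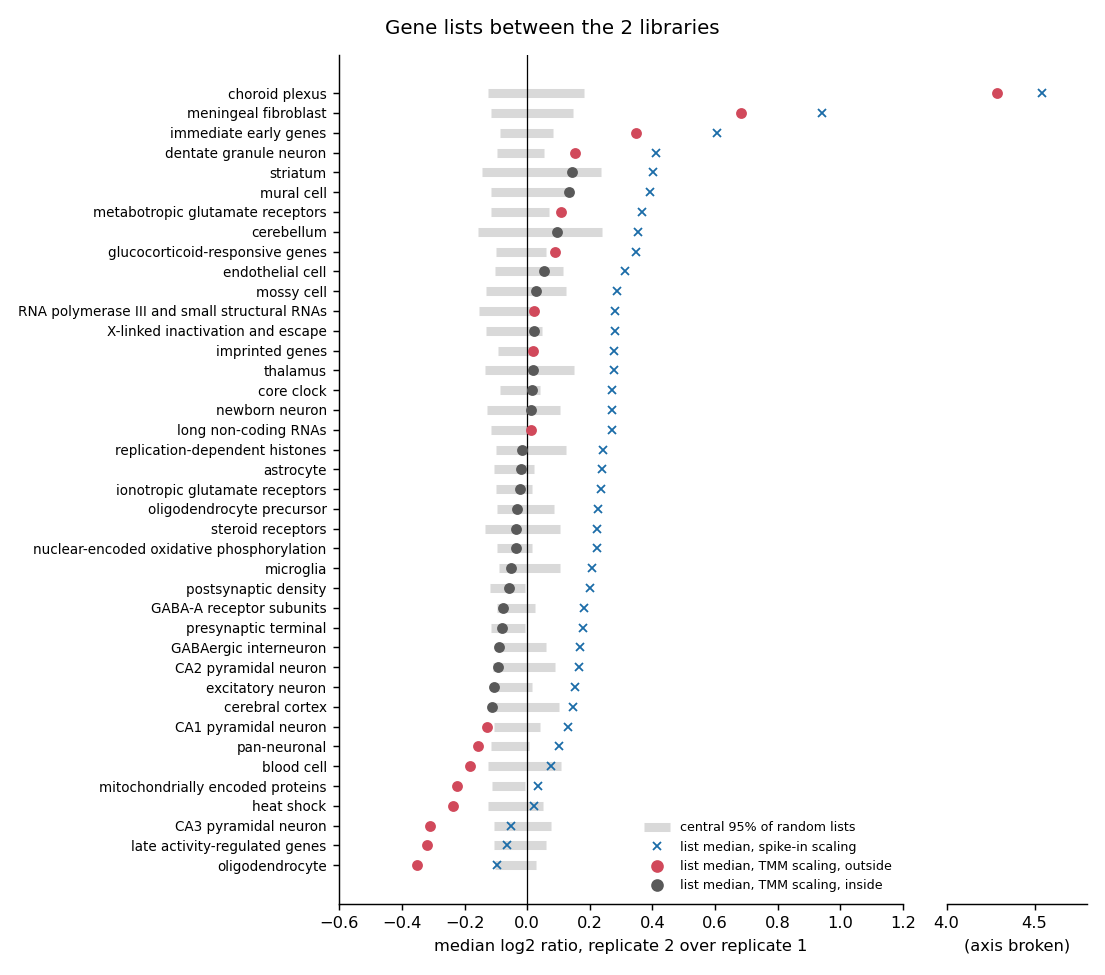
Median log2 ratio of replicate 2 over replicate 1 for 40 gene lists with TMM scaling (red where outside, grey where inside the central 95% of random lists, which the pale bars show) and with spike-in scaling (blue crosses), on a broken x axis. Choroid plexus stands at 4.28 and oligodendrocyte at −0.35, and spike-in scaling moves all lists up by 0.26, which turns, among those outside, the pan-neuronal, CA1, blood, heat shock and mitochondrially encoded lists from below to above 0.

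Among single genes, 59 of 12651 were over 2-fold apart, 47 higher and 12 lower in replicate 2, or 79 higher and 5 lower under spike-in scaling. In both quantifications 40 of them were so, 36 higher and 4 lower. Besides Ttr, Clic6, Slc4a5 and Aqp1, the highest ratios belonged to the serotonin synthesis gene Tph1 (chromosome 7, 46644641 to 46672537), with 4 and 477 counts and a 112-fold difference, Mfrp at 86.2-fold, 1500015O10Rik at 31.1-fold, Tmem72 at 25.7-fold, Col8a1 at 23.5-fold and the tight junction gene Cldn2 at 22.6-fold. Mfrp shares reads, and its log2 ratio was 6.43 in the first and 3.29 in the second quantification. For Tmem72 the values were 4.68 and 0.62. The pseudogene Gm12070, with 0 and 563 counts, was at least 198-fold higher, and 1700047I17Rik2 was 30.8-fold higher, but both share reads. In the second quantification the log2 ratio of Gm12070 was 0.53, and 1700047I17Rik2 had under 1 count in both libraries.

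Lower in replicate 2 in both quantifications were Inhba, the clustered protocadherin genes Pcdhb2 (2.34-fold) and Pcdhb3 (2.30-fold), and the pseudogene Gm2223 (2.27-fold). The last 3 share reads. Gm24497, a small nuclear RNA gene (9.88-fold), Fam177a (6.28-fold), a copy of Nnt (2.73-fold), Nutf2 (2.60-fold) and Gm9531 (2.08-fold) were lower by this rule in the first quantification alone. In the second, Gm24497 had 0 counts in both libraries, and the log2 ratios of the other four were −0.10, −0.78, −0.29 and −0.66. Hist1h2ap, Zc3h11a and Gm20388 had −1.30, −1.22 and −1.10 in the first quantification and 0.34, 0.55 and 0.94 in the second. Of the 19 genes apart in the first quantification alone, 7 had under 1 count in the second in both libraries, so that they could not be apart there. Of the other 12, 11 had shared reads, against 16.7% of all genes compared.

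Transcript usage was compared between the quantifications. For 75.2% ± 0.11 of 7427 genes in replicate 1 and 7486 genes in replicate 2, both named the same major transcript. Between the replicates the major transcript was the same for 92.4% of 7271 genes in the first quantification and 87.3% in the second. Transcripts annotated as retained introns took 8.52% ± 0.55 of the TPM of protein-coding genes. In the panel of 22 neuronal and glial genes, 17 had the same major transcript in both quantifications and both libraries. In the first quantification Snap25-201 took 88.5% ± 1.86 of Snap25, App-201 89.9% ± 0.73 of App, Camk2b-209 83.3% ± 3.39 of Camk2b, Cltb-201 75.7% ± 1.13 of Cltb, Clta-205 72.3% ± 3.02 of Clta, Mbp-211 70.4% ± 0.16 of Mbp, Mapt-204 68.9% ± 2.00 of Mapt and Camk2a-203 65.6% ± 1.15 of Camk2a. The share of Mbp-211 was 34.4% ± 2.00 in the second, that of Clta-205 55.8% ± 3.62 and that of Camk2a-203 52.1% ± 2.40. Of the glutamate receptor genes, Gria1-201 took 57.0% ± 0.60 and 51.0% ± 0.86 in the first and second quantification and Gria2-202 56.0% ± 0.94 and 58.1% ± 0.66. Lowest of the panel in both was Ank3-244 at 19.2% ± 1.23 and 16.6% ± 1.30. The other five were Grin1, Dlg4, Bdnf, Pkm and Ntrk2. For the glycolytic gene Pkm the first quantification put Pkm-202 first at 51.4% ± 0.26 and the second Pkm-201 at 51.2% ± 0.88. For Dlg4 these were Dlg4-203 at 50.7% ± 2.99 and Dlg4-201 at 27.9% ± 0.40.

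Disagreement reached some of the most abundant genes. For the lipid carrier gene Apoe, at 886 ± 38.2 TPM, Apoe-209 took 85.2% ± 0.96 in the first quantification and Apoe-205 92.8% ± 2.02 in the second. Hpca, Cox4i1 and Rpl41 also had different protein-coding transcripts on top. For Gapdh the first quantification chose the non-coding Gapdh-208 at 67.8% ± 0.81 and the second the coding Gapdh-207 at 46.7% ± 7.63. For Rps27 the coding Rps27-201 at 97.8% ± 0.68 stood against Rps27-209 in replicate 1 and Rps27-205 in replicate 2, both annotated as retained introns. Rps27-201 is 345 bases long, close to the fragment lengths of 339.06 and 325.02 bases assumed in the second quantification. Whether this moved the choice was not tested.

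**Figure D4:**
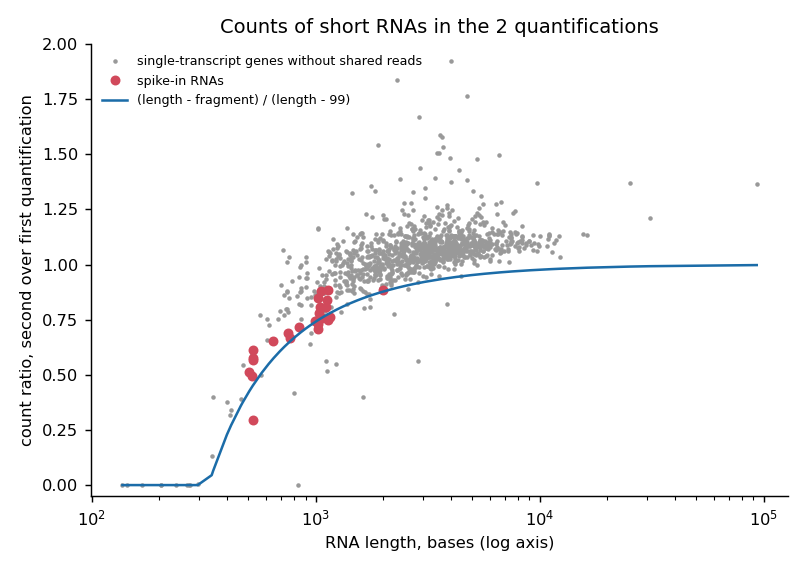
Count in the second over the first quantification against RNA length in bases (log axis) for RNAs with 1 transcript and no shared reads, mean of 2 libraries, with spike-ins in red and the ratio of the 2 effective lengths as a line. The ratio is 0 at the median of the 10 RNAs under 300 bases and 1.10 for the 178 RNAs of 5000 bases or more, and 3 RNAs lie above the plotted range.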

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

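Leaving out the genes over 2-fold apart and counting only genes with whole expected counts or apart in both quantifications were chosen after seeing the data, and the other settings were planned. Of the alternatives for the results of the design, 50 values kept their direction and stayed within the limits set, and 16 moved. The number of genes detected ran from 10446 at 5 TPM to 16840 in the second quantification, and either replicate alone gave 14968 to 15323. Genes of neighbouring and unrelated tissues detected dropped from 43 to 20 at 5 TPM. By TPM in place of counts, protein-coding genes took 40.8%, small structural RNAs 42.5% and mitochondrial RNAs 9.56%, since TPM divides by RNA length. The biological coefficient of variation was 0.179 with spike-in scaling, 0.0797 at a mean count of 100 or more, 0.108 as the median of gene-wise values and 0.0614 without the genes over 2-fold apart. The 59 genes over 2-fold apart became 524 at a mean count of 10 or more and 8 at 500 or more, 170 at 1.5-fold and 26 at 3-fold, and 32 with whole expected counts only, where fewer genes entered. Spike-in scaling gave 84, of which 79 were higher in replicate 2. Major transcripts matched for 74.3% of genes at 1 TPM or more, 71.4% at 100 TPM or more and 85.8% where the first transcript had 2 times the TPM of the next, and the cause of the first pair was not tested. Lists outside random lists numbered 12 to 20 against 17. The GABAergic interneuron list, at percentile 2.54, came outside at 0.23 in the second quantification and at 2.47 with the mean in place of the median. Its place just outside, at 2.48, with the other scalings of counts came from a new random draw, since those scalings move all genes nearly alike. The cortex list came outside in the second quantification, CA2 at a mean count of 500 or more, and the excitatory neuron and core clock lists with the mean. Spike-in scaling adds 0.26 to each median and changed the sign of 14 of the 23 medians inside random lists and of 5 outside, which were pan-neuronal 0.10, CA1 0.13, blood cell 0.077, heat shock 0.021 and mitochondrially encoded proteins 0.033. Metabotropic glutamate receptors changed to −0.028 at a mean count of 500 or more, imprinted genes to −0.00084 with the deposited TPM and long non-coding RNAs to −0.0058 in the second quantification. There, Hist1h2ap, Zc3h11a and Gm20388 also changed sign, to 0.34, 0.55 and 0.94, and the cause was not tested. Whether depth or differences between the samples made the 524 was not tested.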

Other observations

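The tests of the pineal genes, that of shared reads among choroid plexus genes and that of the fragment length were chosen after the result was seen. Several genes known from the pineal gland and from photoreceptors were nearly absent in replicate 1 and present in replicate 2. Gnb3, Crx, Lhx4, Gngt2, Sag, Aanat and Asmt come from a list of 12 pineal genes written before its values were looked at, and the other genes named were chosen after their values were seen. The retinoid-binding protein gene Rbp3 had 1 and 115 counts, the phototransduction genes Gnb3, Pde6g and Pde6c 3 and 120, 10 and 84, and 0 and 25 counts, and Tulp1 1 and 56 counts. Tph1, which makes the serotonin from which the pineal gland forms melatonin, had 4 and 477 counts. The transcription factor genes Crx, Otx2, Lhx4 and Neurod4 had 0 and 38, 14 and 142, 0 and 26, and 5 and 51 counts, Otx2 being also on the choroid plexus list. These are counts of the first quantification. The second gave smaller log2 ratios for several of these genes, among them Crx (1.47 against 6.31), Tulp1 (2.84 against 5.30) and Pde6g (2.23 against 3.08). It gave larger ones for Rbp3 (6.37 against 6.33) and Gnb3 (6.39 against 5.18). Other members of the pineal list differed less, with 22 and 23 counts for Gngt2, 35.1 and 68.1 for Sag, 7 and 17 for Aanat and 1 and 7 for Asmt. TPM stayed low, at most 9.34 for Tph1 in replicate 2.

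Some cerebellar genes followed the same direction at low counts. Gabra6, Cbln3 and Fat2, genes of cerebellar granule cells, had 5 and 22, 12 and 46, and 25 and 96 counts, with log2 ratios of 2.11, 1.97 and 2.00. The cerebellum list had a median of 1.15 at a mean count of 10 or more, at the 100 percentile of random lists, and 0.10 at 100 or more. In a further list of 13 cerebellar genes, chosen after these were seen, the 9 with a mean count of 10 or more had a median log2 ratio of 0.16. Of the 13, 6 already reached 1 TPM in replicate 1, and of the 9, En2 was over 2-fold higher (8 and 21 counts) and Ppp1r17 over 2-fold lower (18 and 6 counts).

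For the choroid plexus genes higher in replicate 2, sharing of reads between similar genes was argued against. All 7 of 7 measured list genes had whole expected counts, so none was treated as sharing reads. In the second quantification these 7 genes were over 2-fold higher too. Neighbouring tissue carried along in general stays open. Of 5 lists for ependymal cells, blood, thalamus, striatum and cortex, 1, the ependymal list at 0.60, had a median above 0.5 over members with a mean count of 10 or more, but the other four already stood at medians of 83.3, 3.72, 3.20 and 10.9 TPM in replicate 1, which could hide a small share, and the meningeal fibroblast and cerebellum lists, outside that test, had medians of 0.63 and 1.15. A candidate explanation is choroid plexus tissue, which lies against the hippocampus in the lateral ventricle, carried into replicate 2. A second list of 12 choroid plexus genes, written before its values were looked at, had a median log2 ratio of 3.21 (3.15 with genes at 0 counts set to 3), with all 12 higher and 10 over 2-fold higher, although 3 of them reached 1 TPM in replicate 1. Its most abundant members in replicate 2 were Igfbp2 at 34.9 and Cab39l at 15.6 TPM, against 1237 TPM for Ttr, and no biological explanation was tested, since age, sex and strain were the same.

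For the pineal genes higher in replicate 2, reads shared between similar genes in one quantification were argued against, since of the 5 list genes with a mean count of 10 or more that were over 2-fold higher in the first quantification, 4 were so in the second. A candidate explanation is pineal tissue carried into replicate 2. In the list of 12 pineal genes, written after Tph1 was seen and without it, the 6 with a mean count of 10 or more had a median log2 ratio of 2.24 with genes at 0 counts set to 3 counts, and 1 of the 12, Gngt2, reached 1 TPM in replicate 1. Its most abundant members in replicate 2 were Gnb3 at 3.20 and Gngt2 at 1.98 TPM, and summed counts were 75.1 and 339. Whether the choroid plexus or another neighbour itself supplied these RNAs stays open, because both sets of genes were higher in the same library, and no biological explanation was tested.

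Short RNAs near 0 in the second quantification formed the third pattern, in which Rn7sk stood at 57645 TPM in the first quantification and 4.77 TPM in the second. Reads shared between copies of short RNAs were argued against as the only cause, since 10 single-transcript RNAs under 300 bases with no shared reads had a median second-to-first count ratio of 0. Rn7sk, Rn7s1, Rn7s2 and Rpph1 share reads and were not among these 10. The test therefore does not decide whether sharing added to their drop. A candidate explanation is a fragment length longer than the RNA. Over 1119 single-transcript RNAs without shared reads, which are not independent replicates, the ratio rose with the one the 2 effective lengths give, with a rank correlation of 0.615, and over the 25 spike-ins among them, none shorter than 505 bases, with 0.906. Because the ratio given by the lengths only rises with RNA length, these rank correlations show a rise with length and do not single out this formula. The observed ratios lay above those given by the lengths from 300 bases up, with medians of 0.849 against 0.684 at 600 to 1000 bases and 1.10 against 0.961 at 5000 bases or more, an excess whose cause was not tested. No biological explanation was tested, since both values come from the same reads.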
